A study of Mus musculus with 28 samples.

How the data were processed

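Hippocampal RNA of wild-type and cbp+/- female mice was measured on 28 Affymetrix Mouse Gene 1.0 ST arrays, which use probes along the length of each transcript. Per the labels, each array held RNA pooled from 3 to 4 mice; the labels' extraction protocol gives 4 mice per pool. TSA was given at 2.4 mg/kg and tissue was taken 75 min later, and novelty began 15 min after TSA and lasted 1 h. Groups came from the sample titles, and the naive and vehicle arrays of a genotype formed 1 control group of 5, as the shared numbering of the titles implies. The values are log2 expression values as deposited by the authors, 1 value per transcript cluster and array. The authors processed and analysed the arrays with GeneSpring GX 11, per the labels' protocols, and used RMA (background correction, normalization and summarization of probes), per the submitters' processing notes; its version and the genome build are not given in the sources used here. The normalization makes arrays comparable in distribution, so a shift shared by most transcripts would not be seen. Values ran from 2.11 to 14.02 and array medians from 5.46 to 5.63. Arrays correlated with each other at 0.8958 to 0.9949, and no 2 arrays were identical.

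The deposited table held 35556 transcript clusters. The platform's gene table gave 1 gene symbol for 21789 of them and several for 1621, and 12146 had no entry and are unnamed here. The gene identifiers of 21698 were found in the RefSeq table of assembly GRCm38.p6, which was used only for names and neighbours and changed 0 symbols. Where a gene had over 1 transcript cluster (999 genes), the cluster with the highest mean over all arrays was kept, which left 19938 genes. The 13767 clusters without a single symbol were tested apart and are only counted. No coordinates are printed, since the build of the array annotation is not known, and Cdkn1a, a gene planned for naming, had no cluster of its own and was not analysed here.

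Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 28 arrays in 1 fit and empirical Bayes variances. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The 13 comparisons were genotype (in controls and over all conditions), TSA in each of the 4 backgrounds, novelty in each genotype, 4 interactions, and naive against vehicle controls from a fit in which these were separate groups. The comparisons, the alternatives, the 34 gene lists and the rule for naming genes were set before the data were examined. The pair of comparisons averaged over backgrounds, the array-set block, the exclusion of 3 arrays with raised choroid plexus markers (mean deviation over 0.9 log2) and the lists of chromatin complexes were chosen after seeing the data. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation. The rule named, per comparison, up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold whose compared arrays did not overlap (overlap was allowed for interactions and for the comparison over all conditions), or the 5 with the smallest p where fewer than 5 passed. To these it added up to 4 members per list and a fixed set of activity, stress and target genes. The same rule was applied to the fit with the block, with 1 sign within every array set that held the compared groups in place of non-overlapping arrays. Unnamed predicted genes were left out. The interactions of Egr2, Plag1 and Fv1 were chosen for naming after their values were seen.

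The replicate numbers of the labels were checked for pairing before fits were compared. Deviations from the group means correlated at 0.62 to 0.87 for same-numbered arrays of the TSA and novelty groups (45 pairs) and at -0.69 to 0.02 for the others. Controls did not follow these numbers: their correlation with same-numbered TSA and novelty arrays was -0.64 to 0.16 (36 pairs), while vehicle controls 3, 4 and 5 correlated at 0.52 to 0.84 with replicates 1, 2 and 3 of the other groups. Array sets 2 to 4 were therefore built from the data, with the naive arrays as set 1; no label names them. With array set as a block the median residual SD fell from 0.184 to 0.126. Since the sets were found in the same values that were then tested, the fit without the block stayed the main one.

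The fits were tested on simulated data in which 200 of 19938 genes were changed. For novelty in wild type 19% of changes of 0.5 log2 and 88% of changes of 1 log2 were recovered, and 67% and 99.5% with the block. Among the unchanged genes 0 and 1 were called, and 4 and 16 with the block. For the averaged TSA comparison 85.5% and 100% were recovered, and 98% and 100% with the block, with 2 and 2 unchanged genes called, and 9 and 10 with the block. In the list test, 1 list of 25 genes shifted by 0.3 was recovered and 0 unchanged lists were called. The simulated genes varied independently, so this says nothing about false list calls where members of a list vary together. Alternatives were vehicle controls only, the label number as a block, only the compared arrays, an intensity trend with a robust prior, repeated quantile normalization, omission of genes below the median level, every transcript cluster, array quality weights and leaving out each replicate. Correlations of fold changes that share controls or array sets were set against 20 simulations of unchanged groups. Up to 100 other splits of the arrays were refitted per comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.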

Results

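Hippocampal gene expression was measured in wild-type mice and in cbp+/- littermates, which carry 1 disrupted copy of the gene for the transcriptional coactivator and histone acetyltransferase CBP. The mice received the histone deacetylase inhibitor trichostatin A (TSA) or its vehicle, and were kept in standard housing or placed for 1 h in an unfamiliar box with tubing and toys (novelty). The 28 arrays fell into 8 groups: for each genotype, 5 standard-housing controls, 3 arrays after TSA in standard housing, 3 after novelty with vehicle and 3 after novelty with TSA. Of the 5 controls of a genotype, replicates 1 and 2 came from naive mice and replicates 3 to 5 from mice injected with vehicle. Each array held RNA pooled from 3 to 4 mice, so the spread between arrays is a spread between pools. Array medians ran from 5.46 to 5.63 on the log2 scale, and 19938 named genes were tested. Values below are log2 fold changes ± SE from the fit over all 28 arrays, with adjusted p, and the number of arrays limits their precision.

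The arrays fell into 4 sets that cut across the groups. The first principal component held 41.6% of the variance, of which array set accounted for 96.6% and group for 5.5%. Set 1 held the 4 naive arrays, and sets 2, 3 and 4 each held 1 replicate of every TSA, novelty and vehicle-control group. Within-set values and values with array set as a block are therefore given beside the results whose calls they change. Called genes were selected by means over the same sets and backgrounds, so signs shared between these are partly built in and are no independent evidence. The array-set block was chosen after the data had been seen. Without it the variance between sets stays in the residual, so 0 called genes does not show that nothing changed. If no gene changed, about 0.05 of the 19938 tested genes would have an unadjusted p under 0.05. Counts below that share, which many comparisons without the block gave, are no sign of remaining signal.

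**Figure D1:**
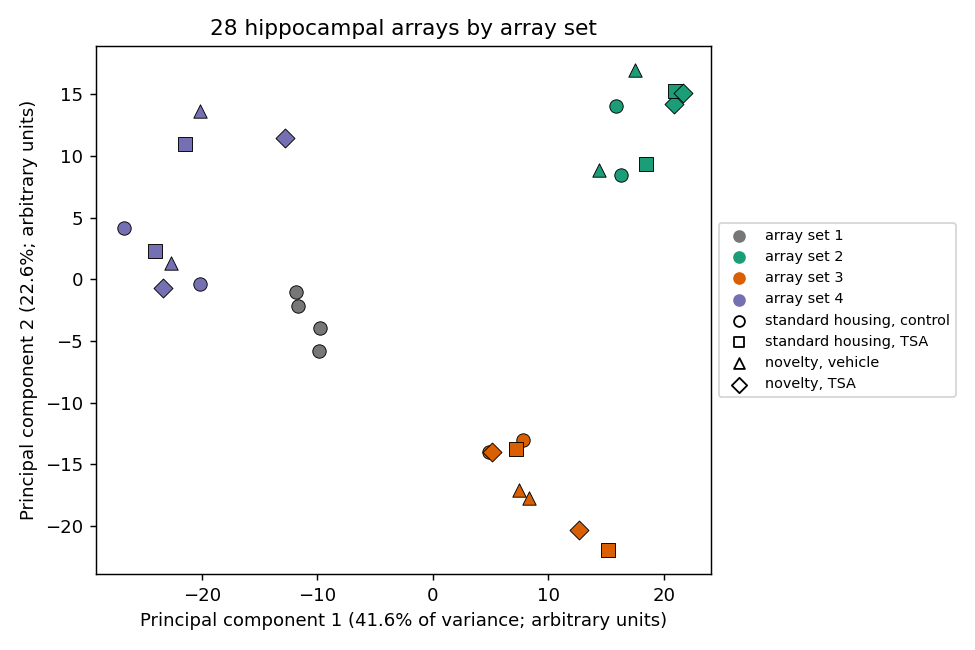
Scores of the 28 arrays on principal components 1 (41.6% of the variance) and 2 (22.6%), in arbitrary units, coloured by array set and with a marker shape per housing and drug. Arrays of one set lie near each other across genotypes and treatments, with a wider spread in set 4. There the wild-type TSA and novelty arrays lie at 10.93 to 13.68 on component 2 and the other arrays at -0.74 to 4.16.

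Crebbp, the gene for CBP itself, was not lower in the arrays labelled cbp+/-. In standard-housing controls its level was 9.29 ± 0.18 (log2, mean ± SD, n = 5) in wild-type arrays and 9.40 ± 0.23 (n = 5) in arrays labelled cbp+/-. Over all conditions the difference was 0.21 ± 0.12 (adjusted p = 1), and 0.21 ± 0.05 with array set as a block (adjusted p = 0.066). Single arrays ran from 8.68 to 9.70 in wild type and from 8.97 to 9.77 in cbp+/-. Where the probes lie relative to the disrupted part of the gene is not given in the sources used here, so this level neither bears out nor contradicts the genotype labels.

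The first comparison asked which transcripts responded to 1 h of novelty. In wild-type mice, 7 genes rose in the novelty arrays (n = 3) against standard-housing controls (n = 5) and no gene fell. Npas4, a neuronal activity-dependent transcription factor, rose by 1.78 ± 0.23 (adjusted p = 0.000809). The immediate early genes Egr2, Fos and Fosb rose by 1.62 ± 0.27 (adjusted p = 0.0214), 1.56 ± 0.20 (0.000809) and 1.23 ± 0.21 (0.0215). Gadd45b, a stress- and activity-induced gene, rose by 1.09 ± 0.20 (adjusted p = 0.0394), Sdf2l1, an endoplasmic reticulum protein, by 0.84 ± 0.15 (0.0389) and Alkal2, a ligand of the ALK receptor kinase, by 0.76 ± 0.13 (0.0214). In cbp+/- mice 5 genes rose and none fell: Egr2 by 1.82 ± 0.27 (adjusted p = 0.00776), Npas4 by 1.48 ± 0.23 (0.00806), Fos by 1.40 ± 0.20 (0.00776), Fosb by 1.34 ± 0.21 (0.00806) and the orphan nuclear receptor gene Nr4a3 by 0.58 ± 0.10 (0.0354). With array set as a block 22 genes rose in wild type and 17 in cbp+/-, and no gene fell. Among the genes added to the calls in both genotypes were Arc, a cytoskeletal regulator of synaptic plasticity (1.22 ± 0.12 in wild type and 1.11 ± 0.12 in cbp+/-), the nuclear receptor gene Nr4a1 (1.10 ± 0.13 and 0.98 ± 0.13) and the immediate early gene Egr1 (0.97 ± 0.14 and 0.80 ± 0.14). Without the block the counts of 7 and 5 became 2 and 0 with vehicle controls only and 1 and 0 with only the arrays compared. With the label number as a block they became 24 (6 of them lower) and 15 (5 lower), and the 5 became 21 (1 lower) with array quality weights. In wild type 2 genes passed without control replicate 1 or 2 or any novelty replicate, and in cbp+/- 0 without novelty replicate 1 and 3 without novelty replicate 2. With the block the 22 became 14 without novelty replicate 3 and 12 without array set 3 in wild type, and the 17 became 11 without array set 2 and 5 without array set 3 in cbp+/-.

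Activity-regulated genes rose as groups in both genotypes. Of 23 measured immediate early transcription factor genes, 4 rose in wild type and 5 in cbp+/- after adjustment over all genes, and 13 and 12 adjusted over the list alone, with median changes of 0.50 and 0.51. This list passed with an estimated correlation between genes too (adjusted p = 0.000623 in wild type and 0.000633 in cbp+/-). Of 34 activity-induced effector genes 1 rose in wild type and 0 in cbp+/- by limma over all genes, and 12 and 8 adjusted over the list alone, with medians of 0.39 and 0.41 (adjusted p = 0.000623 and 0.000633 with an estimated correlation). Of 24 CREB target genes, 1 rose in each genotype, and 5 and 4 adjusted over the list alone, with medians of 0.06 and 0.20 (adjusted p = 0.0234 and 0.0147 with an estimated correlation). Over all genes, 490 had an unadjusted p under 0.05 in wild type and 391 in cbp+/-. These counts lie below the share of 0.05 of the tested genes that chance alone gives.

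Stress-related groups shifted upward as well. Of 20 measured genes of the unfolded protein response, 1 rose in wild type and 0 in cbp+/-, and 2 and 1 adjusted over the list alone, with medians of 0.12 and 0.10 (adjusted p = 0.00223 and 0.0338 with an estimated correlation). In each genotype 25 of 26 glucocorticoid-induced genes had a positive change, with medians of 0.36 in wild type and 0.28 in cbp+/-, while 0 single members passed even when adjusted over the list alone. That call held with an estimated correlation in wild type (adjusted p = 0.0234) and not in cbp+/- (adjusted p = 0.141). With array set as a block the medians were 0.20 and 0.11 (adjusted p = 0.0225 and 0.298 with an estimated correlation). The controls include naive arrays, all in array set 1, while every novelty array came from injected mice. This list was also higher in vehicle than in naive controls. Its medians without the block therefore mix novelty with injection or array set. Heat shock and chaperone genes passed with the preset correlation in both genotypes, at medians of 0.07 and 0.10, but had adjusted p = 0.146 and 0.13 with an estimated correlation. Meningeal and fibroblast markers were lower after novelty in both genotypes, at medians of -0.14 and -0.21 (adjusted p = 0.156 and 0.0523 with an estimated correlation). In cbp+/- choroid plexus markers were also lower, at a median of -0.24 (adjusted p = 0.606 with an estimated correlation). Their mean deviation was 1.39 log2 in cbp+/- control replicate 3, against -0.27 to 0.08 in the other cbp+/- controls. This fall therefore cannot be told apart from choroid plexus tissue in that control array.

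Averaging the novelty effect over genotypes and drug, a comparison added after the data had been seen, set 12 novelty arrays against 16 standard-housing arrays. It gave 38 genes, all higher after novelty, and 95 with array set as a block, 94 higher and 1 lower (Prpf40b, at -0.18 ± 0.04). The 38 became 23 with vehicle controls only, 73 with array quality weights (9 of them lower) and 74 with the label number as a block (18 lower). All 38 were among the 95, and each of the 95 had the same sign within sets 2, 3 and 4. With the block Npas4 rose by 1.70 ± 0.06 (adjusted p = 1.44e-16), Egr2 by 1.40 ± 0.08 (5.47e-12) and Fos by 1.34 ± 0.09 (4.16e-10). Arc rose by 1.18 ± 0.06 (2.04e-12), Fosb by 1.11 ± 0.07 (5.3e-11) and Nr4a1 by 1.10 ± 0.07 (2.49e-11). The MAP kinase phosphatase gene Dusp1 rose by 0.96 ± 0.10, the matricellular gene Ccn1 by 0.89 ± 0.10, Egr1 by 0.87 ± 0.07, the thyroid hormone deiodinase gene Dio2 by 0.71 ± 0.05, Egr4 by 0.67 ± 0.08 and the activin subunit gene Inhba by 0.66 ± 0.07. Smaller rises included Nr4a2 (0.52 ± 0.05), the synaptic scaffold gene Homer1 (0.49 ± 0.05) and the co-chaperone gene Dnajb1 (0.47 ± 0.08). Rises were also seen for Junb (0.43 ± 0.06), the endoplasmic reticulum chaperone gene Hspa5 (0.38 ± 0.05), Errfi1 (0.36 ± 0.06), the clock gene Per1 (0.30 ± 0.07) and the neurotrophin gene Bdnf (0.20 ± 0.04). Of the list members, 15 of 23 immediate early transcription factor genes, 22 of 34 effector genes, 9 of 24 CREB targets, 5 of 20 unfolded protein response genes, 4 of 26 glucocorticoid-induced genes, 3 of 18 heat shock genes and 4 of 18 clock genes rose over all genes. Adjusted over the list alone the counts were 20, 27, 10, 10, 14, 5 and 5. The clock list did not hold (adjusted p = 0.283 with an estimated correlation), while the other 6 did, with the glucocorticoid-induced genes at a median of 0.14 (adjusted p = 0.00784 with an estimated correlation). Meningeal and fibroblast markers had negative values for all 12 genes, at a median of -0.12 (adjusted p = 0.0117 with an estimated correlation).

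**Figure D2:**
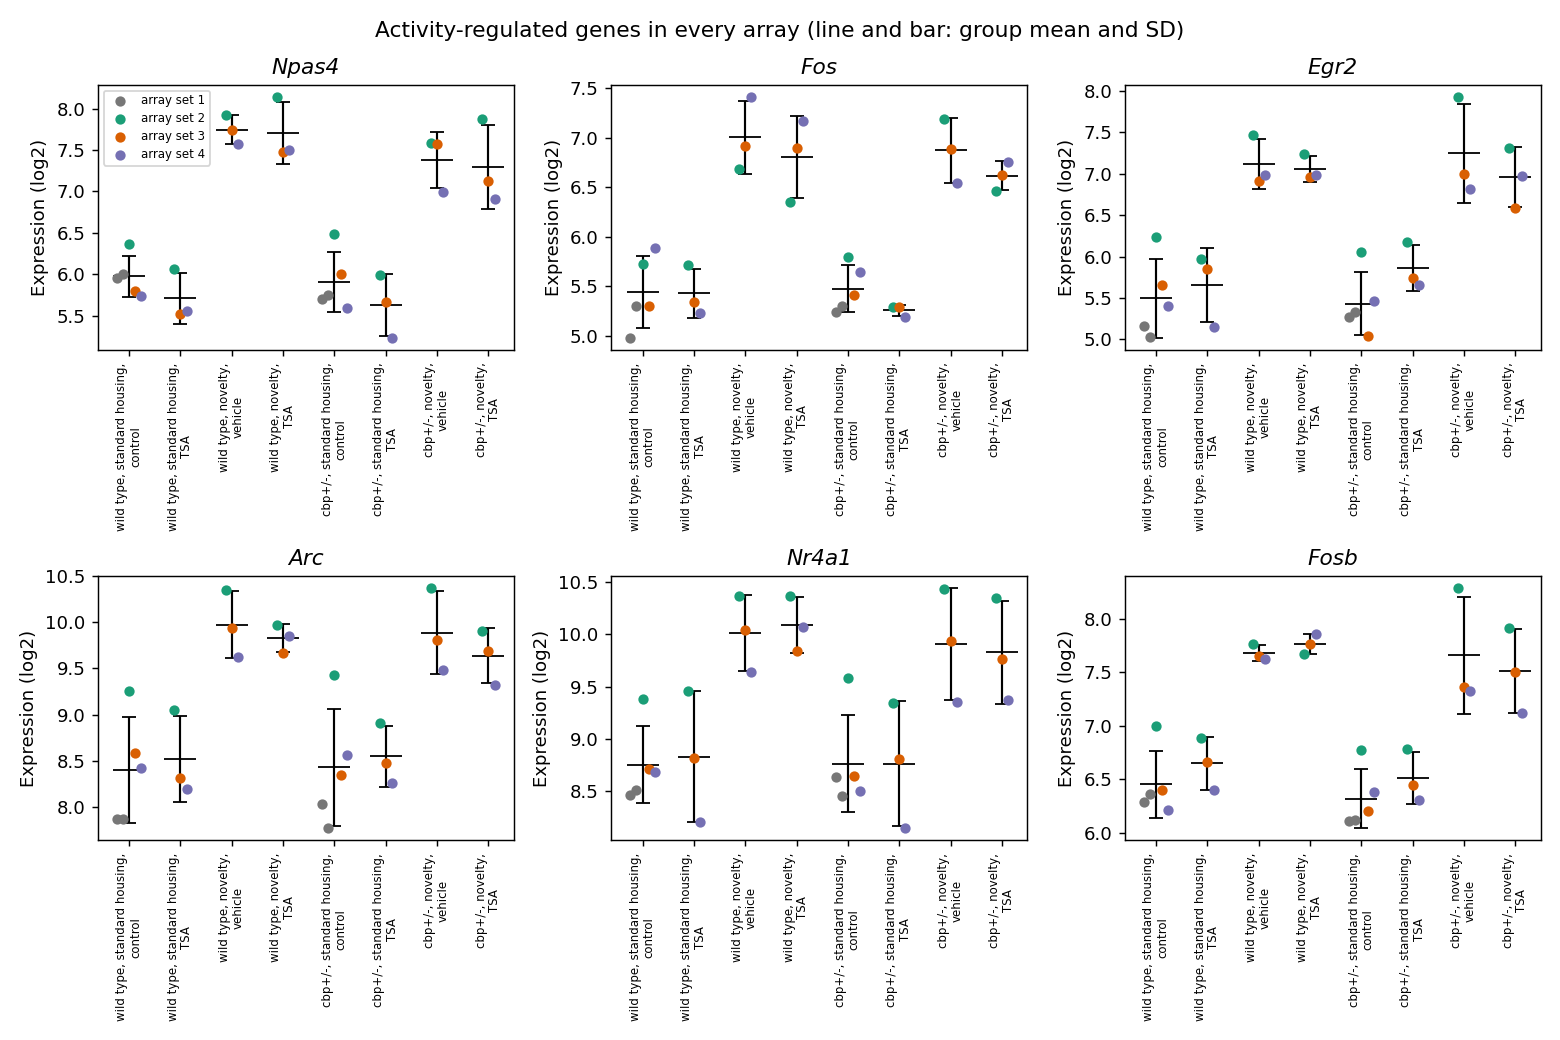
Log2 expression of Npas4, Fos, Egr2, Arc, Nr4a1 and Fosb in every array of the 8 groups, with group mean and SD (n = 5 for standard-housing controls, n = 3 otherwise) as bars and points coloured by array set. The means of the novelty groups lie above those of the standard-housing groups in both genotypes, as for Npas4 at 7.75 ± 0.18 against 5.97 ± 0.25 in wild type.

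The next question was whether the novelty response differed between genotypes. Limma called 0 genes for the genotype by novelty interaction, with 201 genes at an unadjusted p under 0.05, and 0 genes with array set as a block, with 851 at an unadjusted p under 0.05. Over the 38 genes called in the averaged comparison, the median change was 0.50 in wild type and 0.50 in cbp+/-, and 23 of the 38 changes were larger in wild type. Over all tested genes, not only these 38, the lowest adjusted p of the interaction by limma was 1, and 0.781 with the block. The block gave a cbp+/- minus wild-type difference of -0.30 for Npas4 (95% interval -0.61 to 0.01), -0.17 for Fos (-0.66 to 0.32), -0.11 for Arc (-0.44 to 0.22), 0.19 for Egr2 (-0.22 to 0.61) and -0.59 for Dusp1 (-1.12 to -0.06, adjusted p = 0.997). The intervals leave room for sizeable differences in either direction for most of these genes, so a p above the threshold does not show equal responses.

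TSA was examined 75 min after injection of 2.4 mg/kg, in 4 backgrounds. Limma called 0 genes in each of them over all 28 arrays: wild type in standard housing (n = 3 against 5, 1030 genes at an unadjusted p under 0.05), cbp+/- in standard housing (3 against 5, 488 genes), wild type after novelty (3 against 3, 649 genes) and cbp+/- after novelty (3 against 3, 355 genes). With array set as a block 8, 5, 14 and 4 genes passed, and each had the same sign within sets 2, 3 and 4. Fv1, a restriction factor of murine retroviruses, rose by 0.79 ± 0.12 in wild type (adjusted p = 0.00605) and 0.97 ± 0.12 in cbp+/- (0.00034) in standard housing. Plag1, a zinc finger transcription factor, rose by 0.89 ± 0.14 in wild type (adjusted p = 0.00973) and 0.94 ± 0.14 in cbp+/- (0.00768) after novelty. Ptpn2, a protein tyrosine phosphatase gene, fell by 0.63 ± 0.09 in wild type in standard housing (adjusted p = 0.00605) and by 0.53 ± 0.10 after novelty (0.0324). Sox11, a transcription factor of immature neurons, rose by 0.78 ± 0.13 in cbp+/- in standard housing (adjusted p = 0.0305). L3mbtl3, which encodes a reader of methylated histones, rose by 0.71 ± 0.11 in cbp+/- after novelty (adjusted p = 0.00768). Ccne1, which encodes cyclin E1, rose by 0.56 ± 0.10 in the same background (0.0345) and by 0.51 ± 0.10 in wild type after novelty (0.0395). In wild type in standard housing the count of 0 without the block became 3872 with array quality weights, 99 with the label number as a block and 1 with an intensity trend. In cbp+/- it became 7 with array weights, 3 with the label number and 1 with repeated quantile normalization in standard housing, and 2 with array weights after novelty. The counts with the array-set block rested on single arrays. In wild type in standard housing the 8 genes became 0 without TSA replicate 2 and 1 to 4 when any 1 of the other compared arrays except control replicate 5 was left out, and in cbp+/- the 5 became 1 to 3 when any 1 of the compared arrays was left out. After novelty the 14 genes in wild type became 0 without vehicle replicate 3 or TSA replicate 2, 2 without vehicle replicate 2, 6 without TSA replicate 3 and 7 without vehicle replicate 1. The 4 in cbp+/- became 1 without vehicle replicate 2 or TSA replicate 1 or 2, and 11 without TSA replicate 3.

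Averaging over the 4 backgrounds, also added after the data had been seen, set 12 TSA arrays against 16 arrays without TSA. It called 132 genes, 89 higher and 43 lower after TSA. All 132 had 1 sign in the 4 backgrounds, which their selection by the mean over these backgrounds favours. Plag1 rose by 0.70 ± 0.09 (adjusted p = 0.000129), Sox11 by 0.58 ± 0.07 (0.000129), Fv1 by 0.57 ± 0.12 (0.019) and Rest, a repressor of neuronal genes in other cell types, by 0.57 ± 0.09 (0.000877). Further rises were those of Tbc1d31 (0.54 ± 0.09), Tmem159 (0.53 ± 0.11), the RNA-binding protein gene Mex3a (0.51 ± 0.07) and Zfp516 (0.50 ± 0.10). The Wnt pathway gene Dact1 rose by 0.49 ± 0.08, the growth factor gene Fgf9 by 0.48 ± 0.08 and the erythropoietin receptor gene Epor by 0.48 ± 0.07. Kmt5b, a histone H4 lysine 20 methyltransferase gene, fell by 0.61 ± 0.07 (adjusted p = 0.000129). Falls were also seen for Epc2, a subunit of the NuA4 acetyltransferase complex (-0.49 ± 0.10), Gmeb2 (-0.46 ± 0.09), Ing5, an acetyltransferase complex subunit (-0.45 ± 0.09), and the splicing factor gene Srsf6 (-0.44 ± 0.09). Smaller falls were those of Ptpn2 (-0.42 ± 0.06), the ubiquitin ligase gene Siah1b (-0.42 ± 0.06), Lratd1 (-0.40 ± 0.06), Pyroxd1 (-0.40 ± 0.06) and the Mediator subunit gene Med11 (-0.39 ± 0.08). With array set as a block 899 genes passed, 531 higher and 368 lower, among them all 132. Of the 899, 860 had 1 sign in the 4 backgrounds and 890 had the same sign within sets 2, 3 and 4. With the label number as a block it was 567, with more lower than higher genes (275 higher, 292 lower). Leaving out 1 array, without a block, gave 81 to 150 genes. Without the block the count was 461 with array quality weights, 87 without 3 arrays that stood apart in choroid plexus markers and 69 without dim genes. It was 48 without the 4 naive arrays, 730 without them and with the block, and 534 with the block and without the 3 choroid plexus arrays. With the block it was 247 without array set 2, 288 without array set 3, 532 without array set 4 and 585 without cbp+/- novelty TSA replicate 1.

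**Figure D3:**
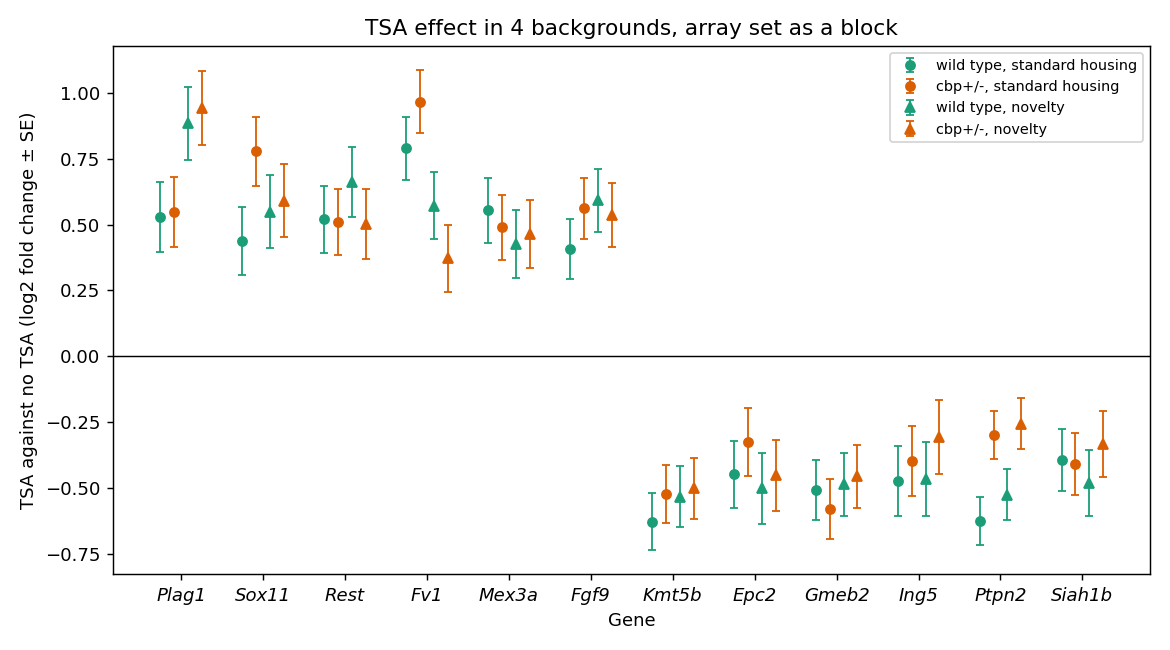
Log2 fold change after TSA for 12 genes in each of the 4 backgrounds, with array set as a block; points are estimates and bars are ± 1 SE (3 TSA arrays against 5 controls in standard housing and against 3 after novelty). Each gene has 1 sign in all 4 backgrounds, as for Plag1, at 0.53 to 0.94, and Kmt5b, at -0.63 to -0.50. The genes were chosen from calls averaged over these backgrounds, which favours a shared sign.

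Averaged over backgrounds 1 of the 34 fixed gene lists passed without the block and 6 with it, and none held with an estimated correlation. Of 16 measured histone genes, H2aj, which encodes a histone H2A variant, rose by 0.24 ± 0.05 (adjusted p = 0.00845), and 3 rose adjusted over the list alone. The list's median change was 0.08 (adjusted p = 0.042, and adjusted p = 0.946 with an estimated correlation). Genes described as induced by deacetylase inhibitors in cell lines did not shift as a list, and with the block 1 of 21 rose, Mxd1 by 0.28 ± 0.06, while Rhob fell by 0.18 ± 0.04 and Tob1 by 0.23 ± 0.05. Of 18 genes described as repressed by such inhibitors, the cell cycle genes Cdc25a and Ccnd2 rose instead, by 0.36 ± 0.06 (adjusted p = 0.00421) and 0.30 ± 0.05 (0.000885), and Ctps, a nucleotide synthesis enzyme gene, fell by 0.20 ± 0.05 (0.041). With the block that list had a median of 0.05 (adjusted p = 0.0473, and adjusted p = 0.649 with an estimated correlation). Among 18 deacetylase and sirtuin genes Sirt1 fell by 0.34 ± 0.07 (adjusted p = 0.0242), and with the block Hdac1 rose by 0.23 ± 0.04 (0.00105). Among 19 acetyltransferase genes and their partners Kat6b and Kat5 fell by 0.19 ± 0.05 (0.0142) and 0.18 ± 0.05 (0.0201) with the block, at a list median of -0.06 (adjusted p = 0.0273, and adjusted p = 0.706 with an estimated correlation). Of 18 clock genes, Cry2 and Cry1 rose by 0.32 ± 0.06 and 0.17 ± 0.05 and Nr1d2 fell by 0.26 ± 0.04 with the block, and the unfolded protein response genes Sesn2 and Creld2 rose by 0.35 ± 0.07 and 0.22 ± 0.04. With the block 0 of 23 immediate early transcription factor genes passed by limma, at a list median of 0.01 (adjusted p = 0.94), and Npas4 had a change of -0.20 ± 0.06 (adjusted p = 0.0605). Of 34 effector genes 3 rose, Plk3 (0.22 ± 0.06), Dusp14 (0.20 ± 0.05) and Siah3 (0.19 ± 0.05), and 2 fell, Plk2 (-0.18 ± 0.04) and Arc (-0.21 ± 0.06, against -0.04 ± 0.17 without the block), at a list median of -0.02 (adjusted p = 0.594). Without the block the direction for Arc changed with array quality weights and on leaving out a replicate. By background and without the block 7 lists passed in wild type after novelty. Choroid plexus markers were higher, at a median of 0.35 with all 14 markers positive (adjusted p = 0.846 with an estimated correlation). Wild-type novelty TSA replicate 1 stood apart for these markers, at a mean deviation of 1.27 log2. Their rise therefore cannot be told apart from choroid plexus tissue in that array. Glucocorticoid-induced genes (-0.13), oxidative phosphorylation genes (-0.13), acetyltransferases and partners (-0.08) and dentate granule neuron (-0.11), astrocyte (-0.07) and oligodendrocyte (-0.20) markers were lower, each at the median given (adjusted p = 0.739 to 0.846 with an estimated correlation). In cbp+/- in standard housing histone genes were higher (0.08) and inflammatory and interferon genes (-0.10) and thalamus markers (-0.12) lower (adjusted p = 0.439 to 0.608 with an estimated correlation), and in wild type acetyltransferases and partners were lower (-0.10, adjusted p = 0.873 with an estimated correlation).

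Whether TSA acted differently by genotype or housing was tested directly. Limma called 0 genes for the genotype by TSA interaction in standard housing, with 198 genes at an unadjusted p under 0.05, and 0 for the TSA by novelty interaction in wild type (191 genes) and in cbp+/- (148 genes). All 3 were also at 0 genes with array set as a block, with 865, 597 and 447 genes at an unadjusted p under 0.05. For Plag1 the change after novelty exceeded that in standard housing by 0.36 in wild type (95% interval -0.04 to 0.75) and by 0.39 in cbp+/- (-0.00 to 0.79). For Fv1 it was smaller by 0.22 in wild type (-0.58 to 0.14) and by 0.60 in cbp+/- (-0.95 to -0.24, adjusted p = 1), all with the block. The sign of the wild-type Fv1 value changed under several alternatives without the block, given in the part on processing. Across genes, which are not independent replicates, TSA fold changes in wild type and cbp+/- had a Pearson correlation of 0.521 in standard housing (jackknife SE over arrays 0.215), where unchanged groups simulated with the array sets kept gave 0.372, and 0.221 after novelty (SE 0.431), where they gave -0.001. With vehicle controls only the standard-housing value was 0.314 against a simulated 0. Between housing conditions the correlation was 0.465 in wild type (SE 0.314) and 0.376 in cbp+/- (SE 0.365), against simulated values of -0.003 and 0.001. Each of these 4 correlations lay within 2 SE of its simulated value, so none is told apart from it at that bound. Those between housing conditions differed from their simulated values by more than their SE. The corresponding covariances were 0.0106 (simulated 0.00616), 0.00375 (-1.29e-05), 0.0103 (-4.94e-05) and 0.00584 (1.63e-05). TSA and novelty effects in standard-housing animals share their controls. Their correlation was 0.468 in wild type and 0.446 in cbp+/-, below the simulated 0.61 and 0.607, with covariances of 0.00978 (simulated 0.0101) and 0.00732 (0.01). It fell to 0.062 and -0.035 when the controls were split between the 2 effects. The split controls come from unlike array sets, which can itself shift this correlation, and no simulated value was made for the split. The fall therefore does not show how much of the correlation came from shared controls.

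The genotype comparison asked which transcripts differed with the loss of 1 functional copy of Crebbp. Limma called 0 genes in standard-housing controls (5 against 5), with 203 at an unadjusted p under 0.05, and 0 over all conditions (14 against 14), with 518 at an unadjusted p under 0.05. With array set as a block the controls still gave 0 genes (826 at an unadjusted p under 0.05). Over all conditions 132 genes passed with the block, 32 higher and 100 lower in cbp+/-. The excess of lower genes did not hold without array set 4, where 14 passed, 8 higher and 6 lower. With no block 8 passed with array quality weights and 1 with repeated quantile normalization. Of the 132, 131 had the same sign within sets 2, 3 and 4. Wfs1, a marker of CA1 pyramidal neurons that encodes an endoplasmic reticulum protein, was lower by -0.41 ± 0.05 (adjusted p = 0.000343), at -0.38, -0.42 and -0.48 within sets 2, 3 and 4. Dusp1 was lower by -0.44 ± 0.10 (adjusted p = 0.0279), at -0.14, -0.25 and -0.98 within the sets. Further lower genes were Igfbp4, an insulin-like growth factor binding protein gene (-0.39 ± 0.06), Efna3 (-0.39 ± 0.09), Plekhb1 (-0.38 ± 0.08), and Pcp4l1 (-0.37 ± 0.07). The same held for the protease inhibitor gene Serpina3n (-0.35 ± 0.08), Lamp5 (-0.35 ± 0.06), Fgf11 (-0.35 ± 0.05), the small GTPase gene Rem2 (-0.34 ± 0.06), the cytokine gene Il33 (-0.34 ± 0.06) and Dcn, which encodes the matrix proteoglycan decorin (-0.31 ± 0.04). The pseudogene Nlrp5-ps was higher by 0.48 ± 0.06 (adjusted p = 9.25e-05), at 0.41, 0.55 and 0.47 within the sets. The protocadherin genes Pcdhb3 and Pcdhb2, members of a family of close paralogs, were higher by 0.43 ± 0.08 and 0.38 ± 0.09. Tmem267 was higher by 0.35 ± 0.07, Anxa4 by 0.35 ± 0.06, the antiviral gene Zc3hav1 by 0.28 ± 0.04, Clec2d by 0.28 ± 0.06, the long noncoding RNA gene Firre by 0.27 ± 0.04 and the von Willebrand factor gene Vwf by 0.27 ± 0.05.

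**Figure D4:**
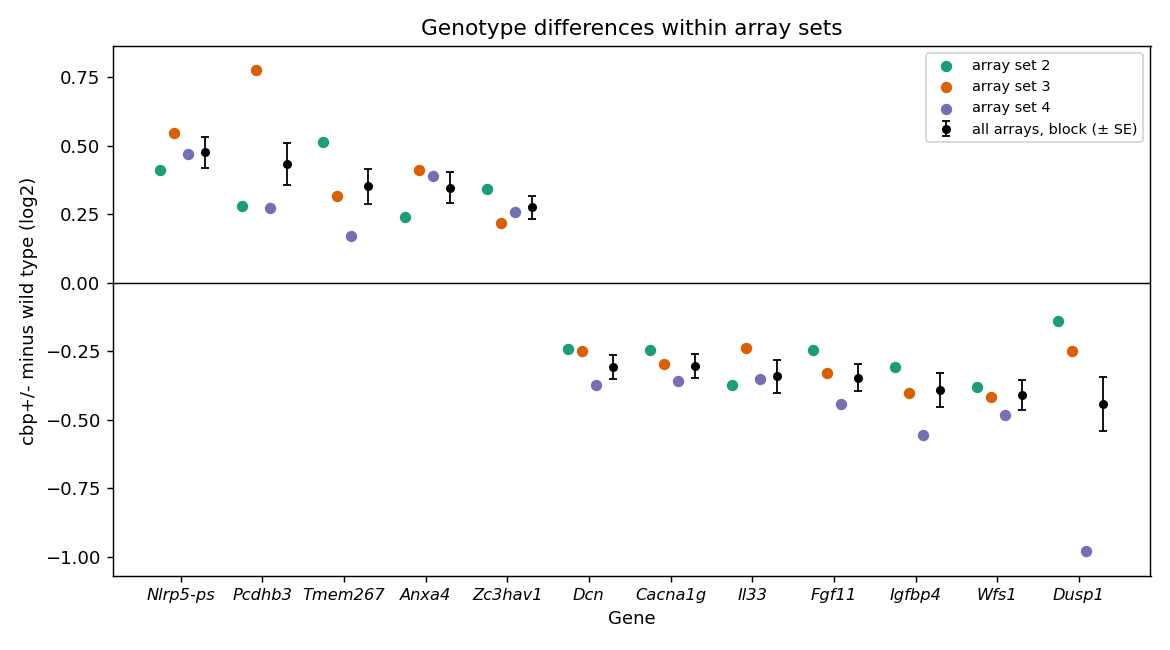
Log2 difference between cbp+/- and wild-type arrays for 12 genes, within array sets 2, 3 and 4 (coloured points) and over all conditions with array set as a block (black points, bars ± 1 SE, 14 against 14 arrays). The within-set values lie on one side of 0 for each gene shown, with the widest spread for Dusp1, from -0.98 to -0.14. A shared sign within the sets was a condition for naming genes by the size of their change, so it is not a result.

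Of the 34 lists 10 passed over all conditions without the block and 0 with an estimated correlation. With the block 15 passed, and again 0 with an estimated correlation. Of 8 measured CA1 pyramidal neuron markers 2 fell, Wfs1 and Mpped1 (-0.17 ± 0.04), and 4 adjusted over the list alone, with a median of -0.13 (adjusted p = 0.0656 with an estimated correlation). Of 13 astrocyte markers 1 fell, Gfap, the astrocyte intermediate filament gene (-0.29 ± 0.06), and 7 adjusted over the list alone, with a median of -0.11 (adjusted p = 0.0656 with an estimated correlation). Of 34 effector genes Dusp1 and the neuropeptide precursor gene Vgf (-0.23 ± 0.05) fell, and 5 adjusted over the list alone, with a median of -0.09 (adjusted p = 0.0656 with an estimated correlation). Of 24 CREB targets the same pair fell, and 6 adjusted over the list alone (adjusted p = 0.0723 with an estimated correlation). Of 26 voltage-gated channel genes 3 fell, the T-type calcium channel gene Cacna1g (-0.30 ± 0.04), Kcnq3 (-0.21 ± 0.04) and Kcna1 (-0.20 ± 0.04), with a list median of -0.02 (adjusted p = 0.53 with an estimated correlation). Choroid plexus markers were higher in the cbp+/- controls, at a median of 0.30 with all 14 positive (adjusted p = 0.489 with an estimated correlation). They stood apart in 3 arrays: wild-type novelty with TSA replicate 1, cbp+/- control replicate 3 and cbp+/- TSA replicate 1, with Ttr, which encodes transthyretin, at 12.28, 12.60 and 12.21 on the log2 scale against a median of 7.55 in the other 25 arrays. Ttr was also raised in some of these, at 11.47 in cbp+/- novelty with TSA replicate 2, 10.91 in wild-type novelty with vehicle replicate 1 and 10.71 in wild-type control replicate 1. The mean deviation over all choroid plexus markers was 0.98 to 1.39 in the 3 arrays and -0.32 to 0.44 in the other 25. Without these 3 arrays and with the block, 118 genes differed by genotype. The block left 78 genes without wild-type or without cbp+/- novelty vehicle replicate 3, 87 and 83 without wild-type and without cbp+/- novelty TSA replicate 3, 54 without array set 3 and 14 without array set 4.

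The controls allowed injected and naive mice to be compared, but all 4 naive arrays form array set 1, so injection and array set cannot be told apart here. Between the 6 vehicle and the 4 naive arrays 480 genes differed, 216 higher and 264 lower after vehicle. The RNA components of RNase MRP and RNase P, Rmrp and Rpph1, were higher by 1.56 ± 0.30 (adjusted p = 0.00627) and 1.11 ± 0.16 (0.000557). Further higher genes were the histone gene H4c6 (1.23 ± 0.20), Tns1 (1.03 ± 0.19), the laminin receptor gene Rpsa (0.93 ± 0.17), Ptgds (0.92 ± 0.23), Arc (0.89 ± 0.23) and the clock gene Ciart (0.87 ± 0.18). Lower genes were Spg20 (-0.85 ± 0.13), the receptor genes Gpr52 (-0.85 ± 0.12) and Npy1r (-0.76 ± 0.10), the transcription factor gene Sox2 (-0.81 ± 0.21), Cdkal1 (-0.79 ± 0.09), Rorb (-0.74 ± 0.13) and the core clock gene Arntl (-0.63 ± 0.11). Of 26 glucocorticoid-induced genes 25 were positive, 4 rose (Tsc22d3 by 0.76 ± 0.19, Ddit4 by 0.66 ± 0.16, Nfkbia by 0.59 ± 0.15 and Hif3a by 0.45 ± 0.11) and 12 rose adjusted over the list alone, with a median of 0.39 (adjusted p = 1.21e-10, and adjusted p = 0.29 with an estimated correlation). Of 21 ribosomal protein genes 4 rose, and 8 adjusted over the list alone (median 0.19, adjusted p = 0.962 with an estimated correlation). Of 27 oxidative phosphorylation genes 3 rose, among them Sdhb by 0.81 ± 0.13 and Uqcrq by 0.82 ± 0.14 (median 0.24, adjusted p = 0.962 with an estimated correlation). With the label number as a block 7176 genes passed (4022 higher, 3154 lower). Among controls these numbers part naive from vehicle arrays, and they do not pair controls with the other groups. That result therefore says nothing about direction. More genes were higher than lower with repeated quantile normalization (587, 306 higher, 281 lower). The count was 1617 with array quality weights and 283 with an intensity trend. It was 112 and 155 without wild-type naive replicate 1 and 2, 119 and 150 without cbp+/- naive replicate 1 and 2, 280 and 290 without vehicle replicate 3 of wild type and of cbp+/-, and 236 without the 3 arrays with raised choroid plexus markers.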

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

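In this part the tests for inherited chromosome sequence, for choroid plexus tissue in any array and for the injection itself were chosen only after the result was seen, as were the block and the averaged comparisons. The spread used to read the cell-share and choroid plexus tests was also chosen after their results were seen, and the bounds of the array-set test of the naive controls were changed then.

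The first pattern is the 132 genotype differences seen with array set as a block, for which chromosome sequence inherited with the mutant allele is argued against, since 1 of the 132 genes lay within 20 Mb of Crebbp. Choroid plexus tissue in 3 arrays is argued against by the size of the changes without them, which was 105.4% of the size with them (jackknife SE 9.0, median 0.239 with, 0.251 without, the same sign in all 132), although 90 of the 132 stayed past the threshold and 42 did not as the median SE rose from 0.047 to 0.051 with fewer arrays; with the choroid plexus marker mean of each of the 28 arrays as a covariate the size was 101% (jackknife SE 4.1) and 119 of the 132 stayed past the threshold. A lower share of CA1 pyramidal cells and astrocytes stays open: with both marker means as covariates the median size was 84.6% of that before (0.239 before, 0.202 after), within 1 jackknife SE (16.8) of the 75% above which it would have been argued against, and 23 of 132 genes stayed past the threshold as the median SE rose from 0.047 to 0.063. Over all tested genes 90 passed with these covariates, the 23 among them. The real split gave the highest count of 100 splits (1 of 100), at 132 genes, but another gave 123, so the margin was narrow. The count also hung on single array sets, at 139 without set 2, 54 without set 3 and 14 without set 4 (8 higher, 6 lower). How far the calls rest on the arrays of set 4 therefore stays open, and the cause was not tested. A biological effect of genotype is among the open explanations and was not separated from a change in cell makeup.

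The 480 differences between naive and vehicle controls are the next pattern. The injection itself could be the source, but 0 naive arrays lay outside array set 1, so injection and array set cannot be told apart. Setting arrays of 1 of the other sets against the remaining ones gave 0 genes for sets 2 and 3 and 3812 for set 4, so a set alone can give more genes than the 480 observed, and the lowest of these counts, 0, decides nothing. Of 100 splits of the 10 controls only the real one gave as many genes (1 of 100, highest other 0). The other splits break up array set 1, so they speak only against a random dealing of single arrays. A difference between array sets, by chance or not, cannot be excluded.

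Other splits of the arrays were refitted for each comparison. For novelty, 1 of 56 splits gave as many genes in wild type (7, highest other 2) and 1 of 56 in cbp+/- (5, highest other 0). These splits ignore array set, and only 8 in each genotype part the sets as the real one does. They therefore do not exclude chance. The averaged novelty comparison gave 38 genes (1 of 100, highest other 3) and 95 with the block (1 of 100, highest other 12). For averaged TSA 2 of 100 splits gave as many, the real one with 132 and another with 1947, which points to a structure of the samples. With the block it was 1 of 100, at 899 against 55. Where the real split gave 0 genes every split gave as many by construction, so the count of splits says nothing about chance. This holds for genotype in controls (100 of 100, highest other 87), genotype over all conditions (100 of 100, highest other 1431), TSA in wild type (56 of 56, highest other 29) and in cbp+/- (56 of 56, highest other 0) in standard housing, and the 4 interactions (100 of 100 each, highest other 0). For TSA after novelty each genotype has 10 splits, too few for a share under 0.05, with 0 genes in the real split and 0 in the highest other (10 of 10). Among splits that part as many pairs of arrays of 1 array set, the highest other was 0 for each of the comparisons with 3 to 5 arrays per group. These were 19 splits for genotype in controls, 8 for each novelty comparison and each TSA comparison in standard housing and 4 for each TSA comparison after novelty, the real one included, too few for a share under 0.05.

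In groups of 5 controls, 26 of 298 sets of values held an array far from the other 4 by Dixon's test; chance alone gives about 1 in 20. Wild-type control replicate 3 stood apart for Fosb (7, others 6.21 to 6.40), Nr4a1 (9.38, others 8.46 to 8.72), Dusp1 (8.40, others 7.18 to 7.41), Cdc25a (5.71), Igfbp4 (8.69), Efna3 (8.90), Fgf11 (7.40) and the mean of the unfolded protein response genes (0.00, others -0.18 to -0.14). Wild-type control replicate 4 stood apart for Dact1 (6.04), replicate 5 for the means of histone genes (0.27) and of endothelial and mural markers (-0.10), and replicate 1 for the mean of choroid plexus markers (0.24). In cbp+/- control replicate 3 the means of immediate early (-0.02), effector (-0.02), CREB target (0.04) and choroid plexus (1.39) genes stood apart, as did Nr4a1 (9.58), Errfi1 (8.96), Plk3 (6.32), Efna3 (8.64), Fgf11 (7.32) and Mpped1 (10.02). In cbp+/- control replicate 5 these were the means of histone (0.17) and microglia genes (0.35) and Zfp516 (5.98), and in replicate 1 the mean of blood cell markers (0.14). Replicate 3 of each genotype is the vehicle control of array set 2.

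Of the interactions, 11 gene list tests passed with the preset correlation and none with an estimated one. For genotype by TSA these were acetyltransferases and partners (median 0.13, adjusted p = 0.011), inflammatory and interferon genes (-0.14, adjusted p = 0.0351), voltage-gated channels (0.12, adjusted p = 0.011) and thalamus markers (-0.17, adjusted p = 0.0148), each with adjusted p = 0.962 with an estimated correlation. For TSA by novelty in wild type these were glucocorticoid-induced genes (-0.25, adjusted p = 1.46e-06), oxidative phosphorylation genes (-0.12, adjusted p = 0.0188) and choroid plexus markers (0.44, adjusted p = 0.000223), each with adjusted p = 0.942 with an estimated correlation. For TSA by novelty in cbp+/- these were immediate early genes (-0.12, adjusted p = 0.0301), effector genes (-0.11, adjusted p = 0.0216) and thalamus markers (0.13, adjusted p = 0.0216), each with adjusted p = 0.924 with an estimated correlation, and striatum markers (-0.16, adjusted p = 0.0321, and adjusted p = 0.488 with an estimated correlation). With vehicle controls only, 0 lists passed for genotype by TSA, and 1 and 0 for TSA by novelty in wild type and cbp+/-. With array set as a block the counts were 5, 2 and 7. Genotype by novelty gave 0 lists, and 1 with either setting. For TSA by novelty only the standard-housing controls include naive arrays, so those values carry any injection or array-set difference too. The choroid plexus value includes wild-type novelty TSA replicate 1, which stood apart for these markers.

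Clusters without a single gene name also passed the threshold, 3 in the averaged TSA comparison and 2 in the averaged novelty comparison.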

How the results depend on the processing

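The array-set block, the choroid exclusion, their combinations with other settings, and all alternatives of the averaged comparisons were tests chosen only after the results had been seen; for each change below the cause was not tested unless fewer arrays or genes were used. Counts are genes past the threshold. The array-set block gave 132 genes for genotype over all conditions, 8, 5, 14 and 4 for TSA in wild type and cbp+/- in standard housing and then after novelty, 22 and 17 for novelty in wild type and cbp+/-, 899 for averaged TSA and 95 for averaged novelty. It left 0 genes for genotype in controls and for the 4 interactions. With this block and vehicle controls only the counts in the same order were 88, then 2, 1, 3 and 2, then 22 and 15, then 730 and 89; with the block and without the choroid plexus arrays they were 118, then 4, 3, 11 and 2, then 26 and 16, then 534 and 90. With vehicle controls only and no block, novelty gave 2 and 0 genes, averaged TSA 48 and averaged novelty 23. The label number as a block (replicate block) gave 99 and 3 genes for TSA in standard housing, 24 and 15 for novelty, 7176 for naive against vehicle (369 of them among the 480), 567 for averaged TSA and 74 for averaged novelty; these numbers do not pair the controls with the other groups. Only the compared arrays gave 1 and 0 genes for novelty. An intensity trend with a robust prior gave 1 gene for TSA in wild type in standard housing and 283 for naive against vehicle. Repeated quantile normalization gave 1 gene for genotype over all conditions and 1 for TSA in cbp+/- in standard housing. Array quality weights gave 8 genes for genotype over all conditions, 3872 and 7 for TSA in standard housing, 2 for TSA in cbp+/- after novelty, 21 for novelty in cbp+/-, 1617 for naive against vehicle, 461 for averaged TSA and 73 for averaged novelty. Without dim genes averaged TSA gave 69, and without the choroid plexus arrays 87 and naive against vehicle 236.

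Leaving out each replicate gave 0 to 1 genes for genotype over all conditions and for TSA in either genotype in standard housing, and 2 to 8 for novelty in wild type (2 without control replicate 1 or 2 or any novelty replicate, 4 without control replicate 4 or 5). For novelty in cbp+/- it gave 0 to 7 (0 without novelty replicate 1, 3 without replicate 2), for naive against vehicle 112 to 451 (112, 155 and 280 without wild-type control 1, 2 and 3, and 119, 150 and 290 without cbp+/- control 1, 2 and 3), and for averaged novelty 28 to 40. For averaged TSA it gave 81 to 150 (84 without wild-type novelty TSA replicate 2, 87 without cbp+/- control 1, 81 without cbp+/- TSA replicate 2, 85 without cbp+/- novelty vehicle replicate 3 and 83 without cbp+/- novelty TSA replicate 1). With the block, averaged TSA ran from 585 (without cbp+/- novelty TSA replicate 1) to 953, and leaving out array set 1, 2, 3 or 4 gave 730, 247, 288 and 532.

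Over the 12 planned comparisons other than naive against vehicle, where 3 lists passed and 0 with an estimated correlation, 54 list tests passed, 9 with an estimated correlation, 87 with the replicate block, and 10 with the array-set replicate block and an estimated correlation. The correlation of TSA effects between genotypes in standard housing moved from 0.521 to 0.281 with the array-set block. Of 1983 comparisons of 149 gene values with an alternative, 1692 kept direction and side of the threshold, 90 lost it, 190 gained it and 11 changed direction. For genotype by novelty these were Fos (-0.327 to 0.035 when leaving out a replicate), Arc (0.105 with array weights, 0.137 without the choroid plexus arrays, -0.356 to 0.137 when leaving out a replicate) and Egr2 (-0.147 to 0.407 when leaving out a replicate). For TSA by novelty in wild type it was Fv1 (0.11 with the replicate block, 0.231 with array weights, 0.039 without the choroid plexus arrays, -0.148 to 0.184 when leaving out a replicate). The last was Arc with averaged TSA (0.179 with array weights, -0.105 to 0.024 when leaving out a replicate). None of these values passed the threshold. How far signal lay above background was not analysed here, so no gene was called absent.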

Other observations

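In this part the lists of chromatin complexes and the tests for a general fall of nuclear regulators and for expression level were written only after the pattern had been noticed. The lists hold genes that prompted them, so their counts and p-values are not independent evidence.

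Subunits of chromatin complexes moved in opposite directions with TSA, averaged over backgrounds and with array set as a block. Of 43 measured subunits of deacetylase corepressor complexes 10 rose and 0 fell (18 and 1 adjusted over the list alone), among them Rest by 0.55 ± 0.07, Sin3a, the scaffold of the SIN3 complex, by 0.40, Rcor1 by 0.30, Sap30 by 0.28 and Hdac1 by 0.23. Of 65 subunits of acetyltransferase complexes 0 rose and 11 fell with limma (4 and 17 adjusted over the list alone), among them Epc2 at -0.43, Ing5 at -0.41, Yeats4 at -0.36, Ing3 at -0.33 and Epc1 at -0.28. Without the block 4 rose and 0 fell in the first list, and 0 rose and 4 fell in the second. The list medians were 0.10 and -0.06 (p = 9.95e-09 and 2.28e-07, and p = 0.0138 and 0.0255 with an estimated correlation).

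Expression level as the cause is argued against, since over all genes the trend of the TSA change with mean expression spanned 0.037 log2, against a difference of 0.155 between the list medians (SD over array sets 0.017). An offset between array sets cancels within a set by design, so the values within sets do not test it. The difference had the sign of the whole in 3 of 3 sets, at 0.162, 0.134 and 0.131. As the lists were written from these same changes, this shared sign was favoured in advance and decides nothing. A general fall of nuclear regulators stays open, since the positive median of the corepressor list, 0.097, restates the rise from which that list was written. A biological effect of TSA on these genes is among the open explanations and was not tested.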
